A study of Arabidopsis thaliana with 64 samples.

How the data were processed

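The labels describe 64 Arabidopsis thaliana samples, 38 of RNA and 26 of chromatin immunoprecipitation (ChIP), and peak lists of 25 ChIP samples were used. The ChIP sample labelled ELF3pro::ELF3-MYC elf3-1 27C replicate 1 was not used here. RNA came from pooled seedlings grown for 10 days in short days, 8 h of light and 16 h of dark, at 12, 22 or 27 °C, per the labels' protocols. The harvest time points of the RNA samples are not given in the sources used here. ChIP seedlings grew for 10 days in short days at 17 or 22 °C and were kept there or moved to 27 °C for 2 h at zeitgeber hour 8, per the labels' protocols. Tagged proteins were pulled down with anti-c-Myc, anti-HA or anti-Flag reagents, and INPUT samples had no pull-down, per the labels.

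RNA libraries were made with the QuantSeq 3' FWD kit and sequenced on an Illumina NextSeq, per the labels' protocols, so each read marks the 3' end of a transcript. The deposited RNA values are raw read counts per TAIR10 gene locus, whole numbers whose totals differ between samples. Reads were aligned with STAR to TAIR10, per the submitters' processing notes, and the counting tool is not given in the sources used here. Each count file held 32833 loci, of which 32548 (99.1%) were found by locus tag in a gene table of the TAIR10.1 assembly, used for symbols and for which genes lie next to each other. Symbols of the gene lists were fixed with their locus tags.

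ChIP reads were processed with Trimmomatic, Bowtie2, Picard, deepTools and MACS2 on TAIR10, per the submitters' processing notes, with versions not given in the sources used here. Peaks were called for each sample on its own, and whether MACS2 had a control is not given in the sources used here. The deposited peak lists hold a fold enrichment ratio over the local background, as MACS2 writes it. They also hold −log10 p-values and −log10 q-values, as the authors' MACS2 run gave them. These values depend on each sample's depth, which is not given in the sources used here, so peaks were ranked within a list and never compared by value between lists. Peak coordinates are those of the deposited TAIR10 lists, counted from 1.

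Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM factors, the quasi-likelihood test and a Benjamini-Hochberg adjusted p under 0.05. Loci with at least 1 CPM in at least 3 libraries were tested, 19587 in the 38-library fit. That fit had terms for the 16 lines, for temperature against 22 °C and for the 4 number prefixes of the sample titles, fitted as batches, and left 17 residual degrees of freedom. All libraries shared the estimate of the spread because 29 of the 33 groups of 1 line and temperature held a single library, 3 held 2 and 1 held 3. The common dispersion was 0.0551. ELF3pro::ELF3-Q21 lines were compared with ELF3pro::ELF3-Q0 lines in a separate fit of the 6 libraries at 22 °C, with 18054 loci. Both interaction tests, of the 27 °C response in elf3-1 lines and in heterologous overexpressors, used the 38 libraries. Data were simulated with a dispersion of 0.05 for every gene and no other differences between lines, temperatures or batches. Known changes were planted only in genes with a mean of at least 5 CPM, so real changes can be harder to find. On these simulated data the elf3-1 comparison recovered 49 of 50 genes at 4-fold, 15 of 50 at 2-fold and 3 of 50 at 1.5-fold. The 27 °C comparison recovered 42 of 50 at 1.5-fold. The elf3-1 interaction recovered 42 of 50 at 4-fold, 5 of 50 at 2-fold and 0 of 50 at 1.5-fold. The Q21 comparison recovered 48 of 50 at 4-fold, 9 of 50 at 2-fold and 0 of 50 at 1.5-fold. Unchanged genes called in these simulations numbered 5 for the elf3-1 comparison, 8 for the 27 °C comparison, 5 for the interaction and 5 for the Q21 comparison.

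The 13 gene lists were EC targets (of the evening complex of ELF3, ELF4 and LUX), morning clock, evening clock, PIF and auxin growth, heat shock, cold response, light harvesting, flavonoid, dark and sugar starvation, flowering, defence, root markers and seed storage markers. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, with p-values adjusted over the lists of a comparison. Lists could share genes, such as PIF4 and PIF5 in EC targets and in PIF and auxin growth, or LUX and ELF4 in EC targets and evening clock. The lists, the tests and the rule for named genes were set before the data were examined. The rule named ELF3 and ELF4, the 6 highest and 6 lowest log2 changes among called genes with a mean of at least 5 CPM, the 4 list members of smallest p and all EC targets in the elf3-1, ELF3-ox and ChIP results. For the ChIP lists it added the 10 shared sites of highest −log10 p with a gene nearby.

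For each peak list, peaks with several summits were merged, organelle peaks were dropped and the 2000 peaks of highest −log10 p were kept. Shared sites were kept ELF3-MYC peaks of replicate 1 at 17 °C that overlapped a kept peak of replicate 2 by at least 1 bp and no kept INPUT peak. Taking replicate 1 as the reference was chosen after seeing the data. The gene table was used here without strand, so a gene counted as near a site when either of its ends lay within 1000 bp of the summit, in place of the start site that had been planned. Shares have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Site genes were set against called genes with Fisher's exact test, two-sided, with all tested genes as the background. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for peaks and figures.

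The alternatives tried were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors in edgeR, no filter, no title prefix, fits on fewer libraries, each library or line left out, 1000 or all peaks kept, summits within 150 bp, other uses of INPUT, gene ends within 3000 bp, and camera with an estimated correlation. Fits and list tests without 2 libraries low in root markers, sites taken from replicate 2 and gene bodies counted as near were added after seeing the data. A motif search at the sites was planned and was not run because no genome sequence was used here. The title prefixes and the lines overlap in part, so a batch effect and a line effect are separated only as far as the fitted terms allow. P-values cover only these samples, and the labels describe single samples for most groups. In the fit of all libraries, 29 of the 33 groups of a line and temperature held a single library. The residual spread of that fit therefore comes mostly from departures from the line, temperature and title prefix terms, not from replicate libraries. A temperature response that differs between lines would be such a departure, and its part in the spread was not tested.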

Results

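Transcript 3' ends were counted in 38 libraries of Arabidopsis seedlings of 16 lines, and the DNA bound by tagged ELF3 proteins was listed as peaks in 25 ChIP samples. ELF3 is a protein of the evening complex, a set of clock proteins with ELF4 and LUX that represses growth and clock genes, and carries a prion-like domain with a polyglutamine (polyQ) stretch. The RNA libraries comprised 3 grown at 12 °C, 15 at 22 °C and 20 at 27 °C. Wild-type Col-0 had 3 libraries, the elf3-1 mutant 2, the elf4-2 mutant 2, the overexpressors ELF3-ox 3 and ELF4-ox 2, and the crosses elf3-1 X ELF4-ox and elf4-2 X ELF3-ox 2 each. BdELF3-ox, which expresses ELF3 of the grass Brachypodium, had 5 libraries, StELF3-ox, with the potato protein, had 3, and ELF3pro::BdELF3, driven by the ELF3 promoter, had 1. ELF3pro::ELF3 lines with a polyQ length of 0, 7 or 21 supplied 5, 3 and 5 libraries. Gene counts per library ranged from 4381010 to 25649275 with a median of 12076203, and 2.64 to 35.1% of reads were not uniquely aligned. Replicate libraries of a group correlated at r = 0.945 to 0.962 across genes, which are not independent replicates, except for BdELF3-ox 27C replicate 2 at 0.862 and 0.866. The labels do not state the genetic background of most transgenic lines, and the 3' tags of a transgene with another terminator are not counted at the native gene. Tags for ELF3 or ELF4 therefore do not check the overexpressors.

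Growth at 27 °C against 22 °C asked which genes follow a warmer ambient temperature in seedlings. HSP90-1, a heat shock chaperone, rose by a log2 change of 1.72 ± 0.16 (SE, n = 20 and 15 libraries), and 17 of the 20 warm libraries lay above every 22 °C library. The heat shock genes MBF1C and HSP70-4 rose by 1.48 ± 0.19 and 1.31 ± 0.19. PIF5, which promotes elongation, rose by 1.09 ± 0.18, LUX by 0.89 ± 0.14, BOA, a relative of LUX, by 0.56 ± 0.07 and the clock repressor TOC1 by 0.49 ± 0.12. ELF3 differed by 0.10 ± 0.12 (adjusted p = 0.560), with a lower mean of 56.2 CPM against 59.9, and ELF4 by 0.22 ± 0.09 (adjusted p = 0.0556), neither past the threshold. The defensin gene PDF2.1 fell by 3.00 ± 0.18, and 19 warm libraries lay below every 22 °C library. The iron transporter IRT1 fell by 2.77 ± 0.64, CYP82C4, a cytochrome P450 gene, by 3.20 ± 0.52, and LHCB1.1, of the light-harvesting antenna, by 2.95 ± 0.27. BGAL7, a galactosidase gene, rose by 2.78 ± 0.25, the floral gene PI by 2.40 ± 0.30 and GLYI7, a glyoxalase gene, by 2.12 ± 0.28. In all, 3462 genes were higher and 3263 lower at 27 °C over all genes (edgeR), and DESeq2 called 3432 and 3570. In the lines whose libraries shared a title prefix 1464 genes were called, and in the Col-0 libraries alone 199.

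By gene list, 4 of 9 measured EC targets rose over all genes and 5 adjusted over the list alone, and the list stood above other genes (camera adjusted p = 0.00173, adjusted p = 0.347 with an estimated correlation). In the evening clock list 5 of 11 members rose over all genes and 6 adjusted over the list alone (adjusted p = 0.00105, adjusted p = 0.0611 with an estimated correlation). FKF1, which targets floral repressors for degradation, rose by 0.58 ± 0.09, but its log2 change was near 0, at −0.00235, in the Col-0 libraries alone, 1 at 22 °C and 2 at 27 °C. In the morning clock list 4 of 11 rose by either adjustment, led by RVE4 at 0.87 ± 0.11 and RVE1 at 1.08 ± 0.18 (adjusted p = 0.0278, adjusted p = 0.347 with an estimated correlation). In the PIF and auxin growth list 10 of 16 rose by either adjustment, with HFR1 up by 1.02 ± 0.24 and EXPA8, a cell wall expansin, by 0.81 ± 0.21 (adjusted p = 0.000766, adjusted p = 0.347 with an estimated correlation). SAUR22 rose by 1.29 ± 0.25, though reads of SAUR genes can be shared with close copies. In the heat shock list 9 of 14 rose over all genes and 10 adjusted over the list alone (adjusted p = 0.000984, adjusted p = 0.347 with an estimated correlation).

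Some cold response, light harvesting and flavonoid genes fell at 27 °C. Of 12 cold response genes 3 fell by either adjustment, the dehydrin LTI30 by 1.18 ± 0.17, KIN1 by 1.97 ± 0.40 and COR15B by 2.24 ± 0.56 (camera adjusted p = 0.0404, adjusted p = 0.412 with an estimated correlation). Of 14 light harvesting genes 5 fell by either adjustment, among them RBCS1A, a Rubisco subunit, by 0.60 ± 0.09 (adjusted p = 0.00816, adjusted p = 0.425 with an estimated correlation). In the flavonoid list 3 of 8 fell over all genes and 4 adjusted over the list alone, F3H by 0.93 ± 0.16, and F3'H rose by 0.43 ± 0.16 (adjusted p = 0.0141, adjusted p = 0.347 with an estimated correlation). Of 6 dark and sugar starvation genes 4 rose over all genes and 5 adjusted over the list alone, DIN2 by 1.91 ± 0.28, while DIN11 fell by 1.33 ± 0.27 (adjusted p = 0.0627). ASN1, an asparagine synthetase of that list, rose by 0.77 ± 0.21, but was −0.36 in the 3 Col-0 libraries alone, short of the threshold. In the flowering list SVP and FLC, which delay flowering, rose by 0.63 ± 0.10 and 0.49 ± 0.12, and FLM and CO fell by 0.40 ± 0.08 and 0.82 ± 0.20 (adjusted p = 0.634). PR5 of the defence list fell by 2.44 ± 0.56 (adjusted p = 0.204 for 5 genes), COBL9 of the root markers by 1.24 ± 0.29 (adjusted p = 0.0570 for 8 genes) and SESA3 of the seed storage markers by 2.86 ± 0.72 (adjusted p = 0.324 for 4 genes). Both libraries low in root markers, BdELF3-ox 27C replicate 2 and ELF3pro::BdELF3 27C, were among the warm libraries.

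Growth at 12 °C against 22 °C rested on 3 cold libraries, 1 each of ELF3-ox, BdELF3-ox and StELF3-ox. The cold-induced genes KIN1 and RD29A rose by 5.46 ± 0.90 and 4.42 ± 1.11, and ADH1, an alcohol dehydrogenase, by 4.00 ± 0.57, each above all 15 libraries at 22 °C in 3 of 3 cold libraries. HSP90-1 fell by 3.62 ± 0.53, its cochaperone gene Hop3 by 4.00 ± 0.52 and HSP70-4 by 2.28 ± 0.50. BOA fell by 1.66 ± 0.17 and PRR7, a morning clock repressor, rose by 2.22 ± 0.61. LHCB2.1, LHCB2.2 and LHCB2.3 rose by 3.68 ± 0.67, 3.37 ± 0.69 and 4.95 ± 0.77, though reads of such close copies can be shared. SAUR22 fell by 3.40 ± 0.95. The seed storage gene CRU3 fell by 5.84 ± 1.33, but its means were near the floor, at 0.256 CPM at 12 °C against 2.79 CPM. For CRU3, 0 of 3 cold libraries lay below all 22 °C libraries. Over all genes 516 were higher and 676 lower (edgeR), and DESeq2 called 821 and 855. The cold response list rose in 5 of 12 genes over all genes and 10 adjusted over the list alone, and its call held with an estimated correlation (camera adjusted p = 9.00e-10, adjusted p = 0.0236 with an estimated correlation). Light harvesting rose in 4 and 7 of 14 genes (adjusted p = 7.03e-05, adjusted p = 0.513 with an estimated correlation), and heat shock genes fell in 3 over all genes and in 9 of 14 adjusted over the list alone, where 1 rose (adjusted p = 0.000413, adjusted p = 0.513 with an estimated correlation). Called genes numbered 340 without the ELF3-ox 12 °C library, 462 without that of BdELF3-ox, 793 without that of StELF3-ox and 5469 without the title prefix term, and 2130 without the 2 libraries low in root markers, left out after seeing the data. All 3 cold libraries shared 1 title prefix with 4 libraries at 27 °C and none at 22 °C, so batch and cold are separated only through the 27 °C libraries.

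Loss of ELF3 was measured in elf3-1 against Col-0 over 22 and 27 °C (n = 2 and 3 libraries). ELF3 tags differed by −0.64 ± 0.32 (SE, adjusted p = 0.393) and ELF4 tags by 0.37 ± 0.23 (adjusted p = 0.476). The clock gene GI rose by 3.94 ± 0.81 (adjusted p = 0.0237), PIF5 by 2.65 ± 0.44 (adjusted p = 0.00481), PRR7 by 2.48 ± 0.59 (adjusted p = 0.0480) and LUX by 1.55 ± 0.34 (adjusted p = 0.0354). Other EC targets missed the threshold, with LNK1 at 2.88 ± 0.80 (adjusted p = 0.101), PIF4 at 2.06 ± 0.76 (adjusted p = 0.218), TOC1 at 0.21 ± 0.31 (adjusted p = 0.810) and BOA at 0.11 ± 0.17 (adjusted p = 0.826), where the mean was 65.2 CPM against 66.2 in Col-0. BBX28, a B-box protein gene, rose by 4.19 ± 0.64, HFR1, an inhibitor of PIF proteins, by 3.58 ± 0.58, the homeobox gene HB-2 by 1.96 ± 0.38 and XTH15, a cell wall enzyme, by 2.77 ± 0.60. In the morning clock list LNK4 rose by 3.48 ± 0.69 and LHY fell by 3.43 ± 0.71. LHY means were near the floor, at 0.187 CPM in elf3-1 and 1.48 CPM in Col-0. The floral repressor SVP fell by 1.40 ± 0.28 and FLC rose 2.46-fold (adjusted p = 0.0370). The highest log2 changes were those of AT1G69570 at 5.34 ± 0.91 and MRD1 at 5.19 ± 0.37, and the lowest was that of the wall-associated kinase WAK2 at −3.23 ± 0.61. For each called gene named here both elf3-1 libraries lay beyond all 3 Col-0 libraries, which chance gives in 10% of genes in a stated direction.

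Over all genes 79 were higher and 58 lower in elf3-1 (edgeR), with 2724 at an unadjusted p under 0.05, and DESeq2 called 170 and 163. EC targets rose in 4 of 9 genes over all genes and 6 adjusted over the list alone (camera adjusted p = 3.07e-08, adjusted p = 0.0327 with an estimated correlation). PIF and auxin growth genes rose in 4 of 16 over all genes and 11 adjusted over the list alone (adjusted p = 5.09e-13, adjusted p = 0.0327 with an estimated correlation). Morning clock genes stood higher (adjusted p = 0.00659, adjusted p = 0.311 with an estimated correlation), as did heat shock genes (adjusted p = 0.000193, adjusted p = 0.321 with an estimated correlation), of which edgeR called 0 of 14 over all genes and 1 adjusted over the list alone. Over the 13 comparisons, 50 of 169 list tests passed with the preset correlation and 5 held with an estimated correlation. Those 5 were cold response at 12 °C, and EC targets and PIF and auxin growth in both elf3-1 against Col-0 and elf4-2 X ELF3-ox against ELF3-ox. Median, mean and test differed in sign in 24 of the 169, none of them called, such as the flowering list in elf3-1 with a median of 0.08 and a mean of −0.05. Few libraries carried the elf3-1 count, which was 2 without the elf3-1 22 °C library, 31 without that at 27 °C, and 43 and 38 without Col-0 27C replicates 1 and 2. Without 2 libraries low in root markers, neither of them of these genotypes, it was 544, including 137 of the 137. The common dispersion, which all comparisons of a fit share, was 0.0385 without them and 0.0551 with all 38 libraries.

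**Figure D1:**
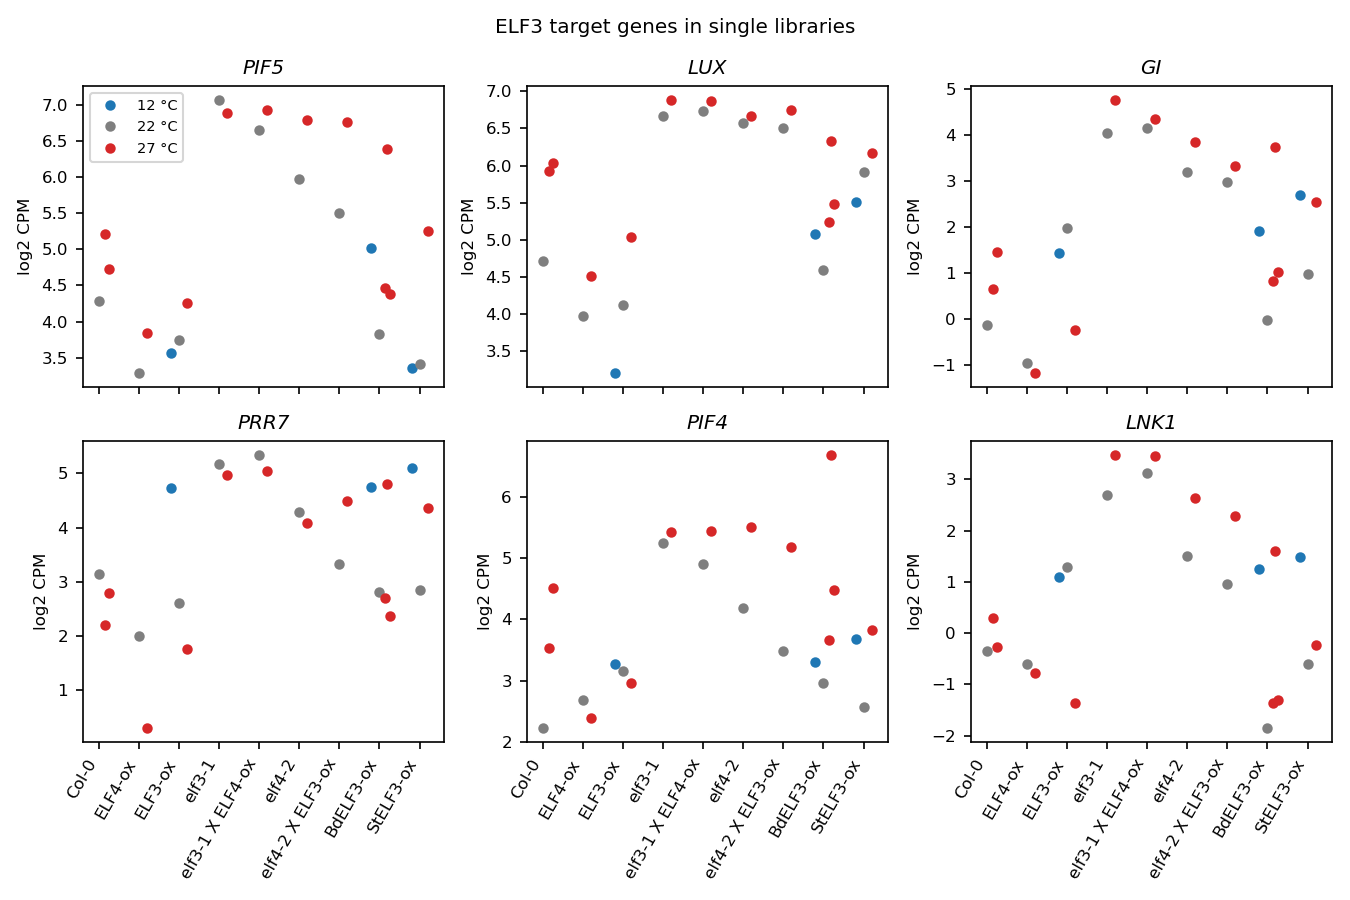
Log2 CPM of PIF5, LUX, GI, PRR7, PIF4 and LNK1 in single libraries of Col-0, mutants, overexpressors and crosses, with colour for growth temperature. All of these genes lay higher in both elf3-1 libraries than in the 3 Col-0 libraries.

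**Figure D2:**
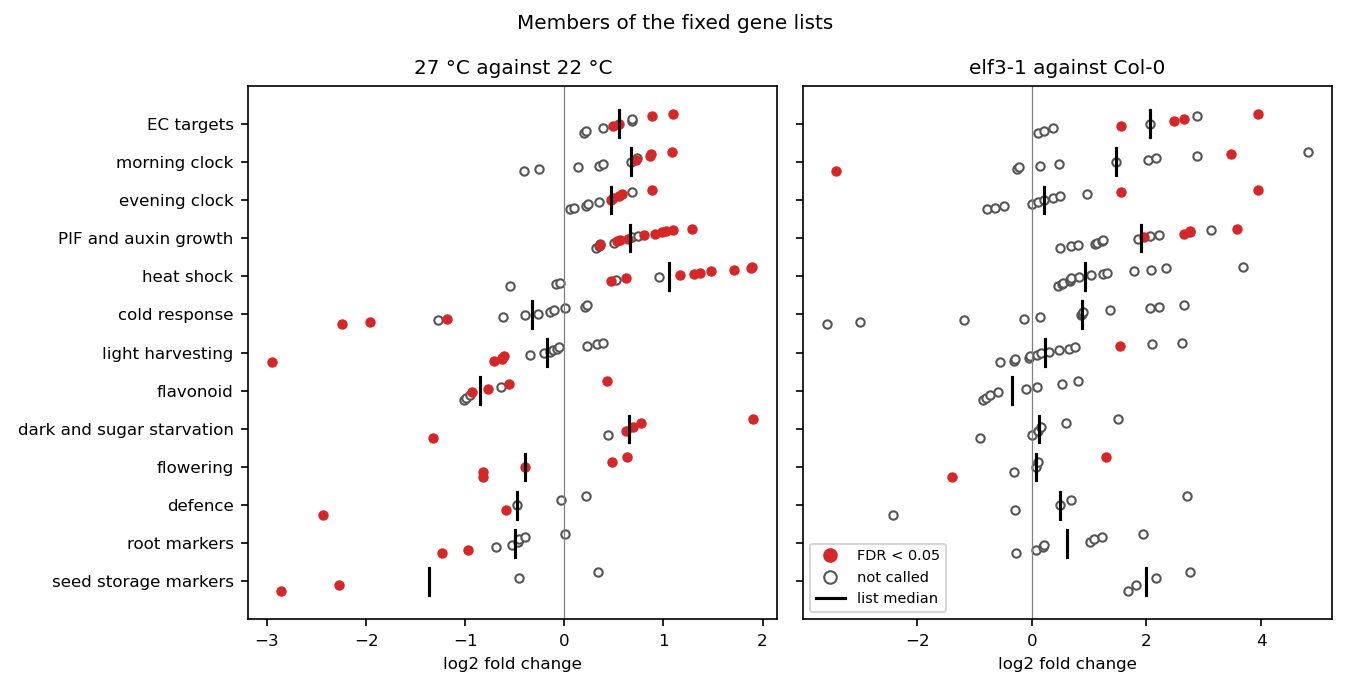
Log2 changes of the members of the 13 gene lists at 27 °C against 22 °C and in elf3-1 against Col-0, with filled points at an adjusted p under 0.05 and bars at list medians. EC targets and PIF and auxin growth genes lay above 0 in both panels.

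Binding of ELF3 was read from ELF3-MYC under its own promoter in elf3-1 at 17 °C, in 2 samples. GI had the peak of highest −log10 p in both lists, on chromosome 1 at 8059296–8062790 (TAIR10) with a fold enrichment of 31.3 in replicate 1. The next shared sites with a gene nearby in that replicate were BBX28 on chromosome 4 at 13674007–13677428 (27.7-fold), CXIP1 and LHCA1 on chromosome 3 at 20340446–20341817 (26.8-fold) and PRR7 with RHL2 on chromosome 5 at 641460–642916 (25.5-fold). LNK1 followed on chromosome 5 at 25675313–25678737 (24.2-fold), then LNK4 at 2166975–2168589 on chromosome 5, LNK3 at 3922956–3924430 on chromosome 3 and PIF4 at 17885535–17886783 on chromosome 2. The list of 10 closed with ELF3 on chromosome 2 at 11055309–11063448, where the line carries an added ELF3 copy, and SLD1 on chromosome 3 at 22784372–22785822. LUX ranked 15 and 7 in the 2 lists, PIF5 23 and 18, TOC1 90 and 80, and ELF4 1159 and 354. BOA ranked 262 in replicate 2 and 2095, outside the kept peaks, in replicate 1. PRR9 ranked 2 in both lists but was no shared site, since its peak overlapped a kept INPUT peak. Of 1963 replicate 1 peaks off the INPUT peaks, 363 (18.5%) were shared with replicate 2, and 84.6% of those 363 had a gene end within 1000 bp of the summit against 70.5 to 73.8% after shifts of up to 20000 bp.

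Genes near shared sites were set against the genes that moved in elf3-1. GI, BBX28, PRR7, LNK4, PIF5, LUX and AT1G69570 were both near a site and higher in elf3-1, as were AT4G25260, AT4G25280 and AT4G25320 of a chromosome 4 stretch where called genes crowd. These stretch genes lay wholly above Col-0 in 12, 12 and 13 of 15 other lines, ELF3-ox among them, so their rise was not particular to elf3-1. They are included in the next count. Of the 79 genes higher in elf3-1, 29 (36.7%) lay near a shared site against 1.72% of the other tested genes (odds ratio 33.2, 95% interval 20.0 to 54.1, Fisher's exact test p = 2.99e-30, two-sided). Without the 2 libraries low in root markers, left out after seeing the data, it was 51 of 287 (17.8%, odds ratio 13.1). Of the 58 lower genes 1 did (Fisher's exact p = 1). Among genes higher at 27 °C 103 of 3462 lay near a site (odds ratio 1.86, interval 1.46 to 2.36, Fisher's exact p = 4.71e-07), and among genes lower 55 of 3263 (odds ratio 0.889, p = 0.478). In ELF3-ox 0 of 6 higher genes (Fisher's exact p = 1) and in elf4-2 0 of 6 higher and 0 of 10 lower genes (p = 1 each) were site genes. The elf4-2 value depended on the fit, with 6 of 24 higher genes near a site without the title prefix term (odds ratio 17.9, interval 5.77 to 47.3, Fisher's exact p = 4.01e-06). It was 8 of 32 without the 2 libraries low in root markers, a fit chosen after seeing the data (interval of the odds ratio 6.94 to 41.7, Fisher's exact p = 9.31e-08). As a list, the 364 tested site genes stood higher in elf3-1 (camera p = 2.07e-09, p = 0.00105 with an estimated correlation). Genes are not independent replicates, and these tests cover 1 set of sites.

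Loss of ELF4 was measured in elf4-2 against Col-0 (n = 2 and 3 libraries). These lines shared no title prefix, so batch and line are separated here only through libraries of other lines. ELF4 tags differed by −0.86 ± 0.27 (SE, adjusted p = 0.544), with a mean of 35.1 CPM against 64.9 and both elf4-2 libraries below all Col-0 libraries, and ELF3 tags by −0.54 ± 0.39 (adjusted p = 0.916), though the mean of ELF3 was higher in elf4-2, at 29.0 CPM against 23.2 in Col-0. Genes of chromosome 4 led the lower calls, with AT4G19500 at −5.44 ± 0.34, AT4G20480 at −5.83 ± 1.08 and VPS54, a vesicle tethering gene, at −2.64 ± 0.21. Higher calls also lay on chromosome 4, with AT4G24420 at 5.97 ± 0.54, TSB2 (AT4G27070), a tryptophan synthase gene, at 3.23 ± 0.52, AT4G27050 at 1.85 ± 0.22 and ECIP1 (AT4G24800) at 1.04 ± 0.20. Elsewhere AT2G15128 rose by 5.29 ± 0.64 and AGP30, an arabinogalactan protein gene, by 3.86 ± 0.76. PIF5 was higher by 2.35 ± 0.53 in both libraries but missed the threshold (adjusted p = 0.117, DESeq2 adjusted p = 0.00848). In all 6 genes were higher and 10 lower (edgeR), with 1192 at an unadjusted p under 0.05, and DESeq2 called 20 and 24. EC targets stood higher, with 0 of 9 called over all genes and 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00106, adjusted p = 0.349 with an estimated correlation). The lower gene was ELF4 itself. PIF and auxin growth genes stood higher, with 0 called over all genes and 5 of 16 adjusted over the list alone (adjusted p = 4.84e-09, adjusted p = 0.162 with an estimated correlation), and so did defence genes (adjusted p = 0.0438, adjusted p = 0.440 with an estimated correlation). Calls numbered 5 without elf4-2 at 27 °C, 8 without elf4-2 at 22 °C, 9 without Col-0 27C replicate 2, 47 without the title prefix term and 58 without the 2 libraries low in root markers, left out after seeing the data.

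Overexpression was measured in ELF3-ox (n = 3) and ELF4-ox (n = 2) against the same 3 Col-0 libraries, so the mutant and overexpressor comparisons share chance values. ELF4-ox shared no title prefix with Col-0, so batch and line are separated there only through libraries of other lines. ELF3 tags in ELF3-ox differed by −0.43 ± 0.34 (SE, adjusted p = 1), though their mean was 27.2 CPM against 23.2 in Col-0, and ELF4 tags in ELF4-ox by 0.70 ± 0.27 (adjusted p = 1). MRD1, a gene named for its response in a methionine mutant, was higher by 5.60 ± 0.39 in ELF3-ox (adjusted p = 2.10e-08) and by 5.77 ± 0.43 in ELF4-ox (adjusted p = 6.69e-08). It was also low in elf4-2, with 0.259 to 6.52 CPM in the Col-0 and elf4-2 libraries and 117 to 269 CPM in all others. Next in ELF3-ox came AT4G25370 at 1.66 ± 0.18, AT4G25315 at 1.45 ± 0.22 and FKBP53, a histone chaperone gene, at 1.41 ± 0.20, each above Col-0 in 3 of 3 libraries. Called genes in ELF3-ox were 6 higher and 0 lower (edgeR, 716 at an unadjusted p under 0.05), against 9 and 1 by DESeq2. In ELF4-ox they were 1 higher and 0 lower (edgeR, 650 at an unadjusted p under 0.05), against 2 and 0 by DESeq2. LUX was lower by −0.79 ± 0.37 in ELF3-ox and −1.18 ± 0.43 in ELF4-ox without passing the threshold (adjusted p = 1 for each). No EC target was called in ELF3-ox, where GI (0.90 ± 0.89), ELF4 (0.23 ± 0.23), PRR7 (0.15 ± 0.61) and PIF4 (0.07 ± 0.80) had positive changes. BOA (−0.36 ± 0.18), LNK1 (−0.10 ± 0.88), PIF5 (−0.07 ± 0.47) and TOC1 (−0.06 ± 0.32) had negative ones, and the group means of PIF4 and LNK1 went the other way. PIF and auxin growth genes stood lower in ELF3-ox (camera adjusted p = 0.00218, adjusted p = 0.555 with an estimated correlation) and in ELF4-ox (adjusted p = 0.000193, adjusted p = 0.456 with an estimated correlation). Heat shock genes stood higher in ELF3-ox (adjusted p = 0.000889, adjusted p = 0.555 with an estimated correlation) and in ELF4-ox (adjusted p = 0.00138, adjusted p = 0.623 with an estimated correlation). Without Col-0 27C replicate 2 the counts were 3 in ELF3-ox and 2 in ELF4-ox, and without Col-0 27C replicate 1 there were 2 in ELF4-ox.

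Defence genes stood higher in ELF3-ox (camera adjusted p = 0.0130, adjusted p = 0.555 with an estimated correlation), with the smallest unadjusted p, 0.0528, at ICS1, which makes salicylic acid (0.57 ± 0.28, SE). Evening clock genes stood lower in ELF4-ox (adjusted p = 0.0256, adjusted p = 0.338 with an estimated correlation), with the smallest unadjusted p, 0.00425, at the clock gene PRR3 (−1.76 ± 0.55).

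The crosses asked whether each protein acts without the other. In elf4-2 X ELF3-ox against ELF3-ox (n = 2 and 3 libraries), LUX rose by 2.33 ± 0.34 (SE, adjusted p = 0.0123) and PIF5 by 2.34 ± 0.43 (adjusted p = 0.0382), each above all ELF3-ox libraries in 2 of 2. ELF4 tags were lower by −1.10 ± 0.23 (adjusted p = 0.115, DESeq2 adjusted p = 0.00391). AT2G05580 rose by 5.41 ± 0.95, and the antenna gene LHB1B1, whose reads can be shared with close LHCB1 copies, fell by 2.09 ± 0.36. Over all genes 5 were higher and 3 lower (edgeR, 866 at an unadjusted p under 0.05), against 24 and 9 by DESeq2. EC targets rose in 2 of 9 genes over all genes and, adjusted over the list alone, 5 were higher and 1 lower (camera adjusted p = 7.11e-08, adjusted p = 0.0387 with an estimated correlation). The lower gene was ELF4 itself. PIF and auxin growth genes rose in 1 of 16 over all genes and 5 adjusted over the list alone (adjusted p = 1.12e-12, adjusted p = 0.0387 with an estimated correlation). The gene called over all genes was PIF5, which is also an EC target. Morning clock genes (adjusted p = 0.000396, adjusted p = 0.114 with an estimated correlation) and seed storage markers (adjusted p = 0.00173, adjusted p = 0.199 with an estimated correlation) also stood higher, the seed storage markers in 1 library only, elf4-2 X ELF3-ox at 22 °C, with SESA3 at 81.3 CPM there, 0.468 CPM at 27 °C and at most 3.44 CPM in ELF3-ox. Of the 5 higher genes 2 lay near an ELF3-MYC site (Fisher's exact test p = 0.00332), as did 1 of the 3 lower genes (Fisher's exact p = 0.0547, p = 0.0451 with 1000 peaks kept). Without the 2 libraries low in root markers, 8 of 17 higher genes (Fisher's exact p = 2.75e-10) and 2 of 8 lower genes (p = 0.00894) did. The 8 calls became 0 without elf4-2 X ELF3-ox at 22 °C, 2, 3 and 4 without ELF3-ox at 12, 22 and 27 °C, 0 without the title prefix term and 25 without the 2 libraries low in root markers.

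In elf3-1 X ELF4-ox against elf3-1 (n = 2 and 2) ELF4 tags were higher by 0.53 ± 0.26 (SE, adjusted p = 0.999) and LUX differed by −0.16 ± 0.41 (adjusted p = 0.999), with means of 112 CPM in the cross and 110 CPM in elf3-1. The root hair gene PRP1 was lower by −5.52 ± 1.28 and SVP higher by 0.93 ± 0.31 (adjusted p = 0.999 for each). PRP1 means were near the floor, at 0.0318 CPM in the cross and 1.92 CPM in elf3-1. The count of called genes was 0 by edgeR, with 480 at an unadjusted p under 0.05, and 1 by DESeq2, and without elf3-1 at 22 °C it was 1 by edgeR. Root markers stood lower (camera adjusted p = 0.00827, adjusted p = 0.729 with an estimated correlation) and flowering genes higher (adjusted p = 0.0200, adjusted p = 0.263 with an estimated correlation).

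Overexpressed ELF3 of other species was set against ELF3-ox. LUX was higher by 1.53 ± 0.38 in StELF3-ox (SE, n = 3 and 3 libraries, adjusted p = 1) and by 0.76 ± 0.35 in BdELF3-ox (n = 5 and 3, adjusted p = 1), with 3 of 3 and 4 of 5 libraries above ELF3-ox. BOA was lower by −0.77 ± 0.16 in BdELF3-ox (adjusted p = 0.837, DESeq2 adjusted p = 0.0464). PIF4 was higher by 1.16 ± 0.75 there (adjusted p = 1). ELF3 tags differed by −0.56 ± 0.30 in BdELF3-ox and −0.20 ± 0.33 in StELF3-ox. The count of called genes was 0 by edgeR in BdELF3-ox, with 475 at an unadjusted p under 0.05 and 3 by DESeq2. It was 0 in StELF3-ox by edgeR, with 315 at an unadjusted p under 0.05 and 1 by DESeq2. In BdELF3-ox light harvesting genes stood higher (camera adjusted p = 1.74e-06, adjusted p = 0.503 with an estimated correlation), and seed storage markers (adjusted p = 0.00408, adjusted p = 0.503 with an estimated correlation) and heat shock genes (adjusted p = 0.0398, adjusted p = 0.553 with an estimated correlation) lower. The 5 BdELF3-ox libraries include 27C replicate 2, low in root markers. Without it and ELF3pro::BdELF3 27C, left out after seeing the data, light harvesting (adjusted p = 0.000487) and seed storage markers (adjusted p = 0.0102) were still called and heat shock was not (adjusted p = 0.229). In StELF3-ox PIF and auxin growth genes and root markers stood higher and light harvesting genes and seed storage markers lower (adjusted p = 0.0296 each, adjusted p = 0.645 with an estimated correlation), and dark and sugar starvation genes lower (adjusted p = 0.0498, adjusted p = 0.645 with an estimated correlation).

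PolyQ length was compared at 22 °C between 2 ELF3-Q21 and 2 ELF3-Q0 lines, each with 1 library. EXPA8 was higher in Q21 by 1.70 ± 0.25 (SE, adjusted p = 0.572), LUX by 1.16 ± 0.36 (adjusted p = 0.594), PIF5 by 0.97 ± 0.31 (adjusted p = 0.594) and PIF4 by 0.75 ± 0.30 (adjusted p = 0.638). ELF3 tags were lower in Q21 by −1.01 ± 0.40 (adjusted p = 0.636), with means of 85.6 against 171 CPM and both Q21 libraries below both Q0 libraries. PolyQ length and the level of ELF3 tags therefore cannot be told apart in this comparison. ELF4 tags differed by −0.25 ± 0.18 (adjusted p = 0.801). CHS, the entry enzyme of flavonoid synthesis, was lower by −0.85 ± 0.20 (adjusted p = 0.572, DESeq2 adjusted p = 0.0462). Called genes numbered 0 by edgeR, with 1298 at an unadjusted p under 0.05, and 12 by DESeq2, 5 higher and 7 lower. PIF and auxin growth genes stood higher in Q21 (camera adjusted p = 7.11e-06, adjusted p = 0.318 with an estimated correlation), as did EC targets (adjusted p = 0.00674, adjusted p = 0.361 with an estimated correlation), light harvesting (adjusted p = 0.00110, adjusted p = 0.272 with an estimated correlation) and root markers (adjusted p = 0.0138, adjusted p = 0.361 with an estimated correlation). Heat shock genes (adjusted p = 0.00110, adjusted p = 0.272 with an estimated correlation) and flavonoid genes (adjusted p = 0.00259, adjusted p = 0.323 with an estimated correlation) stood lower. Leaving out line Q21 #23 gave 139 called genes and leaving out Q21 #7 gave 1, and with no filter on low counts 280 were called. The Q21 #23 library was the only 1 of the 6 polyQ libraries at 22 °C with another title prefix, and this fit had no prefix term, so batch and line cannot be told apart there.

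Differences in the 27 °C response were tested as interactions. In elf3-1 and elf3-1 X ELF4-ox against the other lines, PIF5 responded less by −0.67 ± 0.57 and LUX by −0.45 ± 0.46 (SE, adjusted p = 1 for each). Genes called there numbered 0 by edgeR, with 247 at an unadjusted p under 0.05, and 0 by DESeq2. Seed storage markers (camera adjusted p = 1.64e-06, adjusted p = 0.0866 with an estimated correlation) and PIF and auxin growth genes (adjusted p = 0.0196, adjusted p = 0.750 with an estimated correlation) responded lower. In both elf3-1 lines the 22 and 27 °C libraries had different title prefixes. Batch and temperature response are therefore separated in them only through other lines. In BdELF3-ox and StELF3-ox against ELF3-ox and elf4-2 X ELF3-ox, GI responded more by 2.11 ± 1.05 and PIF4 by 1.29 ± 0.97 (adjusted p = 0.834 and 0.866). Called genes numbered 0 by edgeR, with 1100 at an unadjusted p under 0.05, and 14 by DESeq2. Light harvesting (adjusted p = 0.000805, adjusted p = 0.635 with an estimated correlation), flavonoid (adjusted p = 0.0392, adjusted p = 0.635 with an estimated correlation) and seed storage genes (adjusted p = 0.00635, adjusted p = 0.571 with an estimated correlation) responded higher, the last against a group with the elf4-2 X ELF3-ox 22 °C library named above, and dark and sugar starvation genes lower (adjusted p = 0.000805, adjusted p = 0.571 with an estimated correlation). Without BdELF3-ox 27C replicate 2 and ELF3pro::BdELF3 27C the flavonoid list was no longer called (adjusted p = 0.222), and light harvesting (adjusted p = 0.0272), seed storage and dark and sugar starvation genes (adjusted p = 0.00265 each) were.

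ELF3-MYC binding after 2 h at 27 °C was listed in 1 sample. GI ranked 1, PRR9 3, PRR7 4 and LNK1 5 there, LUX 23, PIF4 28 and PIF5 66. TOC1 had rank 9021 and BOA 15844, outside the kept peaks, and ELF4 had no peak. Of the 363 shared 17 °C sites 74 (20.4%, 95% interval 16.4 to 24.9) overlapped a kept 27 °C peak. The share was 36.5% of 6369 sites with all deposited peaks and 11.2% of 233 sites off every INPUT peak. Of the 1963 replicate 1 peaks, chosen without replicate 2, 363 (18.5%) lay in the other 17 °C list and 99 (5.04%) in the 27 °C list. The exact McNemar test over these peaks gave p = 4.20e-58, with 289 found only at 17 °C and 25 only at 27 °C, but it compares 1 list with 1 list and not the temperatures. At the rank 2000 limit 758 peaks of the 27 °C list were tied. Wider peaks overlap more easily, and the median width of kept peaks was 404 bp in replicate 2 at 17 °C and 161 bp at 27 °C. With summits within 150 bp in place of overlap, the 27 °C share was 19.6% of 296 sites. Over all 25 lists, including 2 of INPUT and the 3 of ELF3-MYC, GI was among the kept peaks of 23, PIF5 and PRR9 of 22, PRR7 of 21, LNK1 of 20, PIF4 of 19, LUX of 18, TOC1 of 12, and ELF4 and BOA of 3 each.

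The other tagged lines found the 363 sites in differing shares. BdELF3-ox found 54.0% of the sites at 22 °C (95% interval 48.7 to 59.2) and 18.5% at 27 °C, ELF3-MYC with ELF4-ox 40.8% at 17 °C and 51.0% at 27 °C, and the StELF3-ox samples 30.9 and 32.2%. Both StELF3-ox samples are labelled 22 °C, but the deposited name of 1 list gives 27 °C, so they are either replicates or a temperature pair. ELF3-ox found 14.3% at 22 °C and 6.06 and 6.89% at 27 °C. ELF3pro::ELF3-Q20 found 28.9% at 22 °C and 14.9% at 27 °C, and ELF3pro::ELF3-Q15 20.9 and 6.06%. ELF3pro::ELF3-BdPrD, with the prion-like domain of the Brachypodium protein, found 27.0% at 22 °C and 16.5% at 27 °C. In another sample pair it found 20.9% at 17 °C and 20.4% at 27 °C. ELF3pro::BdELF3 found 15.4% at 17 °C, 22.0% at 22 °C and 20.1% at 27 °C. The 27 °C list found fewer sites in 6 of 8 pairs of lists of a line and title prefix (exact sign test p = 0.289, two-sided, the smallest possible being 0.00781). The test pooled unlike pairs. Pairs that started at 22 °C, all of prefix 176CS, were all lower at 27 °C, by 8.26 to 35.5 points. Those that started at 17 °C, of other prefixes, differed by 4.68, −0.551 and 10.2 points. Starting temperature and prefix cannot be told apart there. Antibodies differ between lists and their depth is not given in the sources used here, so shares of different lines are descriptions of those lists. Wider peaks overlap a site more easily, and peak widths differed. Kept peaks of BdELF3-ox had a median width of 627 bp at 22 °C, the widest of all lists, and 223 bp at 27 °C. In ELF3pro::ELF3-Q15 the widths were 349 bp at 22 °C and 358 bp at 27 °C, where its share was lower. The part of width in these shares was not tested.

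**Figure D3:**
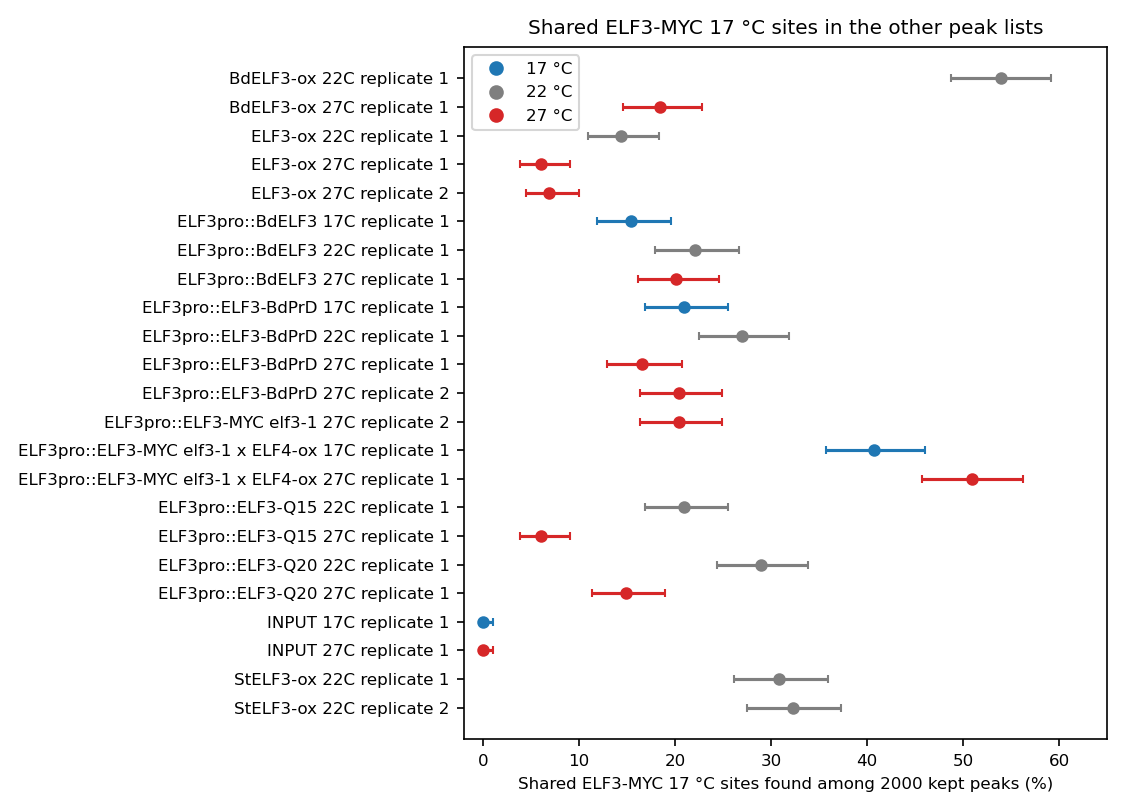
Share of the 363 shared ELF3-MYC 17 °C sites that overlapped the 2000 kept peaks of each other list, with exact binomial 95% intervals for counting error and colour for temperature. BdELF3-ox at 22 °C, whose kept peaks were the widest (median 627 bp), lay highest at 54.0%, and both INPUT lists lay at 0 by construction.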

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

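The depth test and the counts of splits were set before their results were seen, and the genotype test, the groups searched for odd libraries and the tests of crowding on chromosome 4 were chosen only after the result was seen.

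Root markers such as PRP1, PRP3, LRX1, COBL9 and CASP1 were low in BdELF3-ox 27C replicate 2, with a median over 8 root markers of −2.12 log2 CPM, while the other 4 BdELF3-ox libraries lay at 2.22 to 3.48 and the other libraries of BdELF3-ox and StELF3-ox at 22 and 27 °C at 2.21 to 3.19. The value stood apart in both groups by Dixon's ratio, 0.776 of 5 libraries and 0.815 of 6, among 65 group and list pairs, where 3.25 were expected by chance. ELF3pro::BdELF3 27C was also low at −1.96, against 1.57 to 4.00 in the other 36 libraries, and 6 of the 8 root markers were lower in both libraries than in each of those 36. Depth was argued against only as a random loss of reads, since thinning 7 libraries to 4381010 counts left the lowest median at 2.04. CPM are scaled to depth, so thinning could hardly lower them. The BdELF3-ox genotype was argued against for its library by the lowest median of 2.22 in the other 4. Less root tissue in these libraries could also give low root markers, but it was not tested apart from those markers and stays open, as does the genotype of ELF3pro::BdELF3, with 1 library.

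Genes called against Col-0 crowded on chromosome 4. Within 200 consecutive tested genes lay 7 of 16 in elf4-2 (AT4G19490 to AT4G22300, highest of 10000 random draws 5), 4 of 6 in ELF3-ox (AT4G25300 to AT4G25370, highest 3) and 14 of 136 placed in elf3-1 (AT4G25260 to AT4G27520, highest 11), and the p of 1e-04 for each, the smallest the draws can give, argues against chance placement. A difference carried by the Col-0 libraries alone stays open for ELF3-ox. In 0 of the 4 genes did all Col-0 libraries lie outside the range of all others, but 1 overlapping library of any line is enough for that. In these genes 9 to 14 of 15 other lines lay wholly above Col-0, so the test cannot decide. Loss of ELF3 activity stays open for the elf3-1 genes, since in a contrast with ELF3-ox that does not use Col-0, 5 of the 14, FKBP53 among them, did not lie beyond ELF3-ox in the called direction, while BBX28 lay 3.53 above it, and ELF3-ox lay beyond the shared Col-0 libraries in 8 of the 14, with 8 to 14 of 15 other lines wholly beyond them in 11. A linked sequence difference may be carried by some lines, but 4 of 14 elf3-1 genes and 3 of 4 ELF3-ox genes, 3 of them the same, with Col-0, elf4-2 and ELF4-ox on 1 side, and 1 of 7 elf4-2 genes shared by both elf4-2 X ELF3-ox libraries, leave it open.

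Gene lists differed in their 27 °C response between groups of lines. In elf3-1 lines against the others, seed storage markers (camera adjusted p = 1.64e-06) and PIF and auxin growth genes (adjusted p = 0.0196) responded lower. The title prefix changed with temperature in both elf3-1 lines, so batch and response are separated in them only through other lines. In BdELF3-ox and StELF3-ox, light harvesting (adjusted p = 0.000805), flavonoid (adjusted p = 0.0392) and seed storage genes (adjusted p = 0.00635) responded higher and dark and sugar starvation genes lower (adjusted p = 0.000805). None of the 6 held with an estimated correlation, and edgeR called 0 single genes in either interaction, with 247 and 1100 at an unadjusted p under 0.05 and 0 and 14 called by DESeq2. The groups with BdELF3-ox include 27C replicate 2, low in root markers, and without it and ELF3pro::BdELF3 27C the flavonoid list was no longer called in the second interaction (adjusted p = 0.222).

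Other splits of the same libraries were counted for the group comparisons. For 27 °C against 22 °C the 6725 called genes, against at most 389 in the other of 100 splits (value 1), argue against chance. That is the smallest share 100 splits can give, and all splits were fitted at the dispersions of the real labels. The elf3-1 interaction and BdELF3-ox against ELF3-ox called 0 genes, so every split was as large by construction (91 of 91, highest other 1, and 56 of 56, highest other 763), and these counts say nothing about chance. For BdELF3-ox a split that put BdELF3-ox 27C replicate 2 with both 12 °C libraries gave those 763, which points to a structure of the samples. The splits were too few for a share under 0.05 at 12 °C against 22 °C (1 of 4, real 1192, highest other 0), ELF3-ox (1 of 10, real 6, highest other 0), StELF3-ox (10 of 10, real 0, highest other 0) and the interaction of heterologous overexpressors (3 of 3, real 0, highest other 0).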

How the results depend on the processing

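The fits and list tests without BdELF3-ox 27C replicate 2 and ELF3pro::BdELF3 27C, the sites taken from replicate 2 and the count of gene bodies were tests chosen only after the result was seen. DESeq2 called more genes in elf3-1 (333), elf4-2 (44), ELF3-ox (10), ELF4-ox (2), elf3-1 X ELF4-ox (1), elf4-2 X ELF3-ox (33), BdELF3-ox (3), StELF3-ox (1), the interaction of heterologous overexpressors (14) and Q21 against Q0 (12). Without the title prefix term the counts were 5469 at 12 °C, 47 in elf4-2, 3 in ELF4-ox, 0 in elf4-2 X ELF3-ox and 1 in BdELF3-ox. Without the 2 libraries low in root markers they were 2130 at 12 °C, 544 in elf3-1, 58 in elf4-2, 3 in ELF4-ox and 25 in elf4-2 X ELF3-ox. No filter gave 3 in ELF4-ox and 280 in Q21 against Q0, all 13 polyQ libraries gave 2, and the 2 genotypes alone gave 1 in ELF3-ox. At 27 °C lines that shared a title prefix gave 1464 and Col-0 alone (1 and 2 libraries) 199, with FKF1 near 0 at −0.00235 and ASN1 at −0.36, neither past the threshold. Leaving out 1 library or line gave 340 to 793 genes at 12 °C, 2 to 135 in elf3-1, 5 to 14 in elf4-2, 3 to 5 in ELF3-ox, 1 to 2 in ELF4-ox, 0 to 1 in elf3-1 X ELF4-ox, 0 to 6 in elf4-2 X ELF3-ox and 0 to 139 in Q21 against Q0. Named calls weakened in 137 of the leave-one-out results and stayed in 161. They weakened in 22 and stayed in 30 results of lines that shared a title prefix, in 15 and 105 without the title prefix term, and in 10 and 15 with the 2 genotypes alone. Most named 27 °C calls also weakened in the Col-0 libraries alone, with 1 library at 22 °C. Estimated correlations left 5 of 50 list calls. All deposited peaks gave 6369 shared sites and a 27 °C share of 36.5%, and sites off every INPUT peak gave 233 and 11.2%. Within 3000 bp the ELF3-ox odds ratio of site genes was 5.94 (Fisher's exact p = 0.180) in place of 0. Site genes among higher elf4-2 genes were 6 of 24 without the title prefix term (odds ratio 17.9) and 8 of 32 without the 2 libraries in place of 0 of 6, those among the lower elf4-2 X ELF3-ox genes passed with 1000 peaks kept (Fisher's exact p = 0.0451) and without the 2 libraries (p = 0.00894), and the elf3-1 odds ratio was 13.1 without the 2 libraries in place of 33.2. Without the 2 libraries 48 list tests passed in place of 44 of 156. The cause was not tested. No paired analysis was possible by replicate number because the groups compared share fewer than 2 of them, and the 14 lines with libraries at 22 and 27 °C were paired through the line term of the fit. The motif search with 250 bp was not run, and gene starts were replaced by gene ends.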

Other observations

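The sign test of temperature pairs was a test chosen only after the result was seen, and the test of lower ranks was set before.

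GI, PRR9 and PRR7 ranked within the first 5 peaks of ELF3-MYC in both 17 °C lists and at 27 °C, and LNK1 ranked 6, 4 and 5. BdELF3-ox at 22 °C found 54.0% of the shared sites, and ELF3-MYC with ELF4-ox found 51.0% at 27 °C against 40.8% at 17 °C, from 1 list each.

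Of the 363 shared sites 289 were missing from the kept 27 °C peaks. A candidate explanation is that peaks were still called there at lower ranks, and 47.8% of the missing sites (138 of 289) overlapped a 27 °C peak of any rank, against 23.9 and 32.2% after shifts, short of the over 50% set beforehand. The shift to 27 °C for 2 h may also lower binding. The exact sign test over 8 pairs gave p = 0.289, with all pairs from 22 °C lower at 27 °C and those from 17 °C mixed. Depth, antibody yield and the single 27 °C list cannot be told apart from the shift. As a hypothesis, ELF4 overexpression may keep ELF3 on its sites at 27 °C, which replicate ChIP of ELF3-MYC with and without ELF4-ox at both temperatures, in 1 batch with equal depth, would test.

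MRD1 was called in elf3-1, ELF3-ox and ELF4-ox against the same Col-0 libraries. It was low in elf4-2 too (0.259 and 0.961 CPM), and all other lines lay at 117 to 269 CPM. The cause was not tested, and sequencing DNA of each line would show whether a sequence difference separates Col-0 and elf4-2 from the rest.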
